A study of Mus musculus with 24 samples.

How the data were processed

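Total RNA from the lungs of 24 mice in 5 groups was sequenced by the authors after removal of ribosomal RNA. The deposited table gives transcript abundance as TPM, a length-normalized measure, scaled by the authors so that the genes of each library add up to the same total, with 1 column per library and values rounded to 2 decimals. The submitters' notes name HISAT2, StringTie, RSEM and DESeq2 and the mouse genome build GRCm39, with no version and no annotation release. The table holds 78298 genes, of which 21883 carry no symbol. It holds no read counts, so the depth of each library is unknown, no counting interval can be given for any value, and no test that needs counts could be run.

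Expression was analysed as log2(TPM + 1). Genes with a TPM of 1 or more in at least 4 libraries were tested, which left 17823 genes. The pseudocount of 1 makes the fold changes of genes at low levels smaller than the ratio of their TPM values. A linear model with 1 mean per group was fitted to all 24 libraries with limma 3.58.1 (R 4.3.3) with moderated, two-sided tests that used a trend of the variance with expression and a robust prior. The comparisons were LPS against control, each of the 3 extract doses against LPS alone, any dose against LPS alone (1 F-test), a linear trend over the 4 challenged groups, and the high dose against the low dose. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and a gene passed at an adjusted p of 0.05. Fold changes are log2 values throughout, and levels are mean TPM with the SD between mice.

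Values that share a fixed total move together when 1 abundant transcript changes. Each fit was therefore repeated after dividing each library by its median-of-ratios factor, and its counts stand beside those from the TPM as deposited. The word scaled is used for that fit. Other alternatives were upper-quartile scaling, an absolute log2 fold change of 1 or more, no filter, a mean TPM of 1 or more as filter, sample quality weights, a fit to the compared groups alone, the replicate number as a block, a pseudocount of 0.1 without a filter, and leaving out each library in turn. The comparisons, tests, gene lists and these alternatives were fixed before the data were examined, in a form that used count models if counts had been deposited and limma otherwise.

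The 32 gene lists hold 476 symbols, of which 447 were measured. Each list was tested against all other genes with camera at a preset correlation of 0.01 (128 tests, adjusted over the lists within a comparison) and again with the correlation estimated from the libraries. Camera compares the mean moderated statistic of a list's members with that of the other genes. This statistic divides a change by its spread between mice. A score per library, the mean over a list's members of log2(TPM + 1) centred on the mean of all libraries, was compared between groups with a two-sided exact permutation test over all assignments. Pathway sets came from the annotation columns of the deposited table.

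Named genes followed a rule. For each comparison with the control or with LPS alone they were the 8 largest increases and the 8 largest decreases among genes that passed, had a mean TPM of 1 or more and showed no overlap between the libraries of both groups. Predicted genes without a proper symbol and immunoglobulin or T cell receptor segments were skipped, and where fewer than 4 genes passed in a direction the demand for no overlap was dropped. In each list they were the 4 largest changes that passed, or the 2 most abundant members where none passed. They were also the 5 largest moved-back genes per dose, the 5 smallest p in the trend and any-dose tests, and the 3 smallest p where no gene passed. Genes named outside this rule are said to be so where they appear.

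An LPS-changed gene counted as moved back by a dose when it passed in both comparisons with opposite signs. Both comparisons share the LPS libraries, which by itself gives a negative correlation. The counts were therefore set beside those expected from independent lists and those of 100 simulations without any dose effect. In the simulations all challenged libraries, LPS included, took the LPS mean plus deviations shuffled over all challenged groups. The deviations were taken from the mean of each group, so the simulations held no shift of whole libraries between groups. Both comparisons shared the simulated LPS group, and the real LPS libraries were not held fixed. A further 20 fits split the LPS libraries so that each comparison used its own part. Each count was also recomputed for 100 splits of the samples into groups of the same sizes. The fit was tested on simulated data with noise drawn independently for each gene and library. In these data 100 genes were moved by a log2 fold change of 1 and 100 by 2. For LPS against control it recovered 76 and 89 of them, with 5 false calls among 170, and for the high dose against LPS 79 and 96, with 9 false calls among 184. Of 100 genes planted as moved back by the high dose, 94 were found, with 1 false call. The simulated data held no shift of whole libraries and no correlation between genes. The false calls found in them therefore do not carry over to libraries that have either.

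Transcript lengths were those of the longest annotated transcript of each gene in GENCODE M21, an older annotation matched by gene identifier, which covered 14201 of 14234 protein-coding genes tested. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.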

Results

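Gene expression was measured in lung tissue of 24 mice of the C57BL/6 strain, 7 weeks old, in 5 groups. The labels give male sex, which the sex-linked transcripts argue against. An aqueous extract of the mugwort Artemisia argyi (AEAA) was given in the drinking water for 28 days at 0.5 mg/mL (low dose, n = 5), 1 mg/mL (mid dose, n = 5) or 1.5 mg/mL (high dose, n = 5). On day 29 these mice and an LPS group without extract (n = 5) received bacterial lipopolysaccharide (LPS), a trigger of acute lung inflammation, into the trachea at 5 mg/kg. A control group (n = 4) received saline according to the protocol, although the sample characteristics list the LPS challenge for these mice too. Lungs were taken 8 h after the challenge. The table gives TPM only, so the depth of each library is unknown. Between 14996 and 16954 genes reached a TPM of 1 in a library, and no pair of libraries held identical values.

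LPS was compared with control to describe how challenged lungs without extract differed. The secretoglobin Scgb1a1, the main secreted protein of airway club cells, fell from 282000 ± 51800 TPM (SD, n = 4) in control lungs to 48800 ± 12000 TPM (SD, n = 5) in LPS lungs (log2 fold change −2.56, adjusted p = 2.6e-07). This transcript alone took 28.2% ± 5.21 (SD, n = 4) of all TPM in control lungs and 4.88% ± 1.2 (SD, n = 5) after LPS. Slc7a11, which imports cystine for glutathione synthesis, rose from 0.19 ± 0.0337 to 12 ± 6.55 TPM (log2 fold change 3.24, adjusted p = 3.6e-07). Serpina3n, a protease inhibitor of the acute phase, rose from 26.5 ± 0.642 to 620 ± 395 TPM (log2 fold change 4.15, adjusted p = 3.9e-05). Of 17823 genes, 10344 passed, 10013 higher and 331 lower. The median log2 fold change of all genes was 0.55, and after scaling 4978 genes passed, 2455 higher and 2523 lower. Both fits shared 2785 calls of the same sign, and 250 genes passed with opposite signs. The libraries of both groups did not overlap for 9123 genes (51.2%) in the TPM as deposited, where chance gives 1.59% for a single gene. Their median-of-ratios factors did not overlap either, with 0.6454 to 0.8008 in control and 1.083 to 1.269 in LPS libraries. A shift of whole libraries moves many genes together, so the chance value does not judge this count.

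The spread between LPS mice was wide for Il1b, the cytokine of the inflammasome. It rose from 5.28 ± 1.1 TPM (SD, n = 4) to 167 ± 127 TPM (SD, n = 5), with an adjusted p = 0.019 that was 0.08 after scaling. Of the 21 measured inflammatory cytokines and chemokines 8 rose, 1 when adjusted over the list alone, and 1 after scaling. The count of 8 was 3 without Control replicate 1, Control replicate 3, Control replicate 4, LPS replicate 1 or LPS replicate 5, 4 without Control replicate 2 and 5 without LPS replicate 3. When adjusted over the list alone it was 2 without LPS replicate 3 and 7 without LPS replicate 4. The neutrophil alarmin subunit S100a9 rose by 4.04 on the log2 scale (adjusted p = 0.0046, scaled 0.037), and Ngp, a neutrophil granule protein, by 4.27. Of 20 neutrophil markers 18 rose, 19 when adjusted over the list alone and 10 after scaling, with a median 2.64 above that of all genes. Among 24 genes of LPS sensing and the NF-kB pathway 23 rose, 24 when adjusted over the list alone and 11 after scaling. Nfkb2, a subunit of the NF-kB transcription factor, went from 9.38 ± 1.43 to 56.8 ± 24.7 TPM. The list test put this pathway above other genes with an adjusted p = 0.0248 (scaled 4.5e-05). It had an adjusted p = 0.998 with an estimated correlation, and it no longer passed without LPS replicate 1 (adjusted p = 0.0809), LPS replicate 3 (adjusted p = 0.0697) or LPS replicate 5 (adjusted p = 0.0657). All 11 leukocyte adhesion molecules rose, 11 when adjusted over the list alone and 7 after scaling, among them the integrin subunits Itgam (log2 fold change 3.47) and Itgb2 (2.50).

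The challenged libraries did not form 1 level of inflammation. The neutrophil chemokine Cxcl2 lay between 0.09 and 1.37 TPM in LPS replicates 4 and 2, AEAA_low replicate 1, AEAA_mid replicates 1 and 4 and AEAA_high replicates 1 and 4, against 0.06 to 0.27 TPM in control libraries. These 7 libraries were spread over the groups, 2 with LPS alone, 1 at the low dose, 2 at the mid dose and 2 at the high dose. The mean of Cxcl2 in LPS lungs was 99.5 ± 119 TPM (SD, n = 5). Tnf reached 0.47 to 1.65 TPM in the same 7 libraries and up to 64.46 TPM elsewhere. Scgb1a1 took 5.31% and 3.13% of TPM in LPS replicates 2 and 4, against 4.66% to 6.46% in the other LPS libraries. Slc7a11 was 18.26 and 18.23 TPM there, against 2.73 to 11.43 TPM. Their changes from control were thus not confined to lungs with high Cxcl2. For them LPS cannot be told apart from another difference between control and challenged mice, such as the hour of collection. Cxcl2, Saa3, Tnf and the libraries were singled out after their values were seen.

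**Figure D1:**
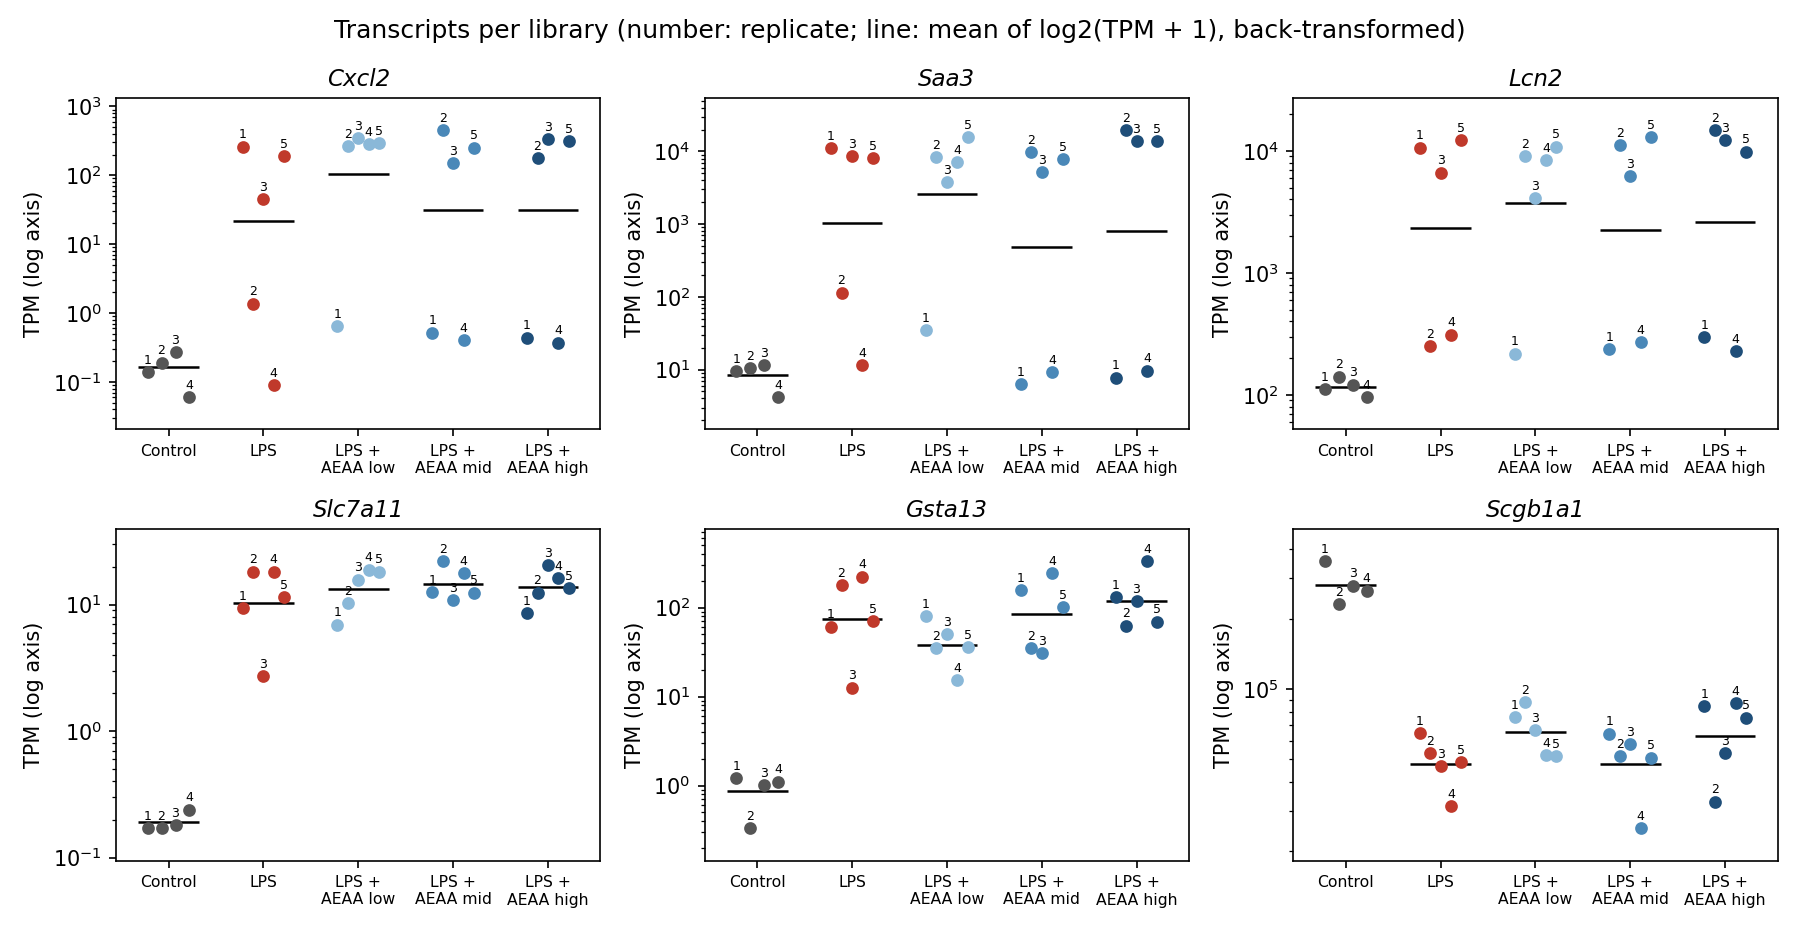
Levels of Cxcl2, Saa3, Lcn2, Slc7a11, Gsta13 and Scgb1a1 in each library by group, in TPM on a log axis, with the replicate number at each point and a line at the mean of log2(TPM + 1), back-transformed. Challenged libraries include 7 with Cxcl2 between 0.09 and 1.37 TPM, while Slc7a11 in those 7 lay between 6.94 and 18.26 TPM against 0.17 to 0.24 TPM in control libraries.

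Of 20 genes of the NRF2 antioxidant response, which guard against oxidants, 16 rose, 16 when adjusted over the list alone and 9 after scaling, where 2 fell. The score of this list was 0.534 and 0.585 in LPS replicates 2 and 4, which had low Cxcl2, against −0.139 to 0.349 in the other LPS libraries. The increase was thus not confined to the lungs with high Cxcl2. The heme oxygenase Hmox1 rose from 23.8 ± 2.53 TPM (SD, n = 4) to 137 ± 54.5 TPM (SD, n = 5). G6pdx, which supplies NADPH, rose from 13.4 ± 1.28 to 59.6 ± 11.7 TPM (log2 fold change 2.06, adjusted p = 2.1e-08). Gsta13 and Gsta1, a pair of closely related glutathione transferase genes, rose by 5.33 and 4.69 on the log2 scale, and how reads were shared between such copies is unknown. Cyp1a1, the target enzyme of the aryl hydrocarbon receptor, fell from 32.2 ± 4.08 to 4.5 ± 4.97 TPM (log2 fold change −2.96, adjusted p = 0.00032). Its list of 15 xenobiotic genes had 4 that rose and 4 that fell, 4 and 4 when adjusted over the list alone, and 1 and 4 after scaling. That list's median was 0.23, its mean −0.10 and its test pointed down (adjusted p = 0.0083, scaled 0.0747, adjusted p = 0.998 with an estimated correlation), a call that was lost after scaling.

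The clock genes split into increases and decreases. The activators Bmal1 and Npas2 rose, Bmal1 from 0.865 ± 0.163 TPM (SD, n = 4) to 18.4 ± 5.32 TPM (SD, n = 5) with a log2 fold change of 3.33 (adjusted p = 9.1e-08), and Npas2 by 2.28 (adjusted p = 1.2e-07). Nfil3, a repressor in the same circuit, rose by 2.92. Dbp, an output gene of the clock, fell from 212 ± 11.1 to 17.8 ± 13.4 TPM (log2 fold change −3.71, adjusted p = 0.00029). Of 17 clock genes 5 rose and 8 fell, 6 and 8 when adjusted over the list alone, and 4 and 10 after scaling. The list test pointed down with an adjusted p = 0.000191, and did not pass after scaling (adjusted p = 0.0573) or with an estimated correlation (adjusted p = 0.317). The labels give no hour of the day for any mouse.

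**Figure D2:**
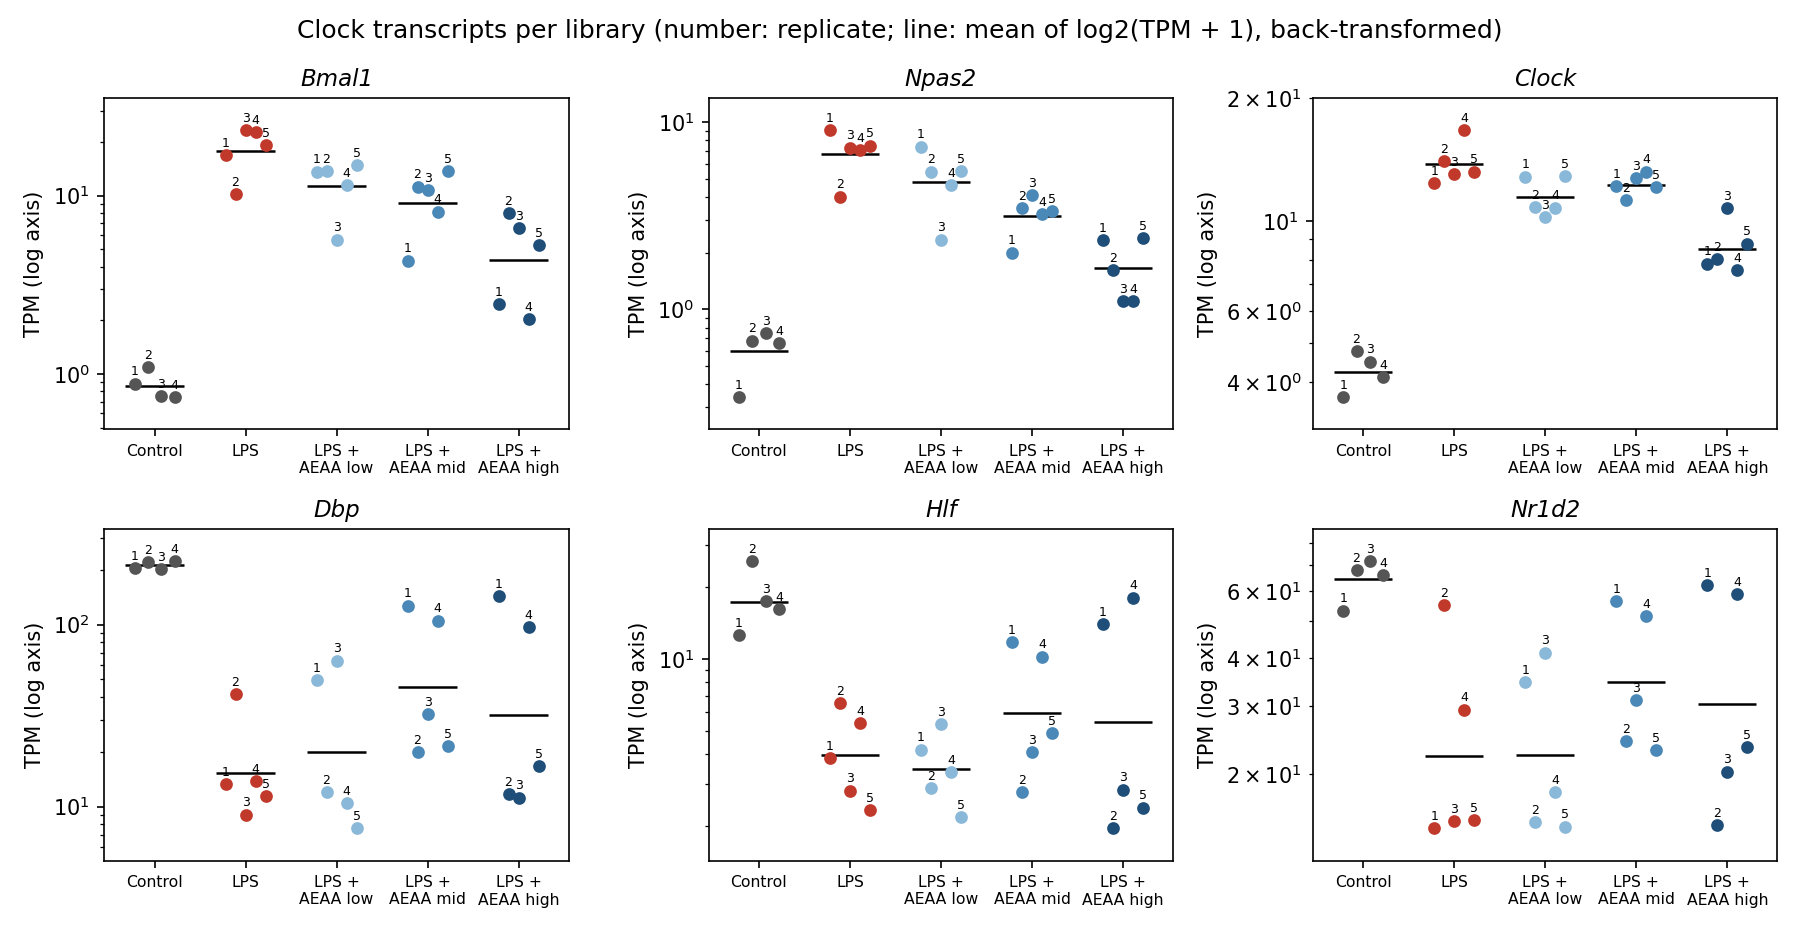
Levels of Bmal1, Npas2, Clock, Dbp, Hlf and Nr1d2 in each library by group, in TPM on a log axis, with the replicate number at each point and a line at the mean of log2(TPM + 1), back-transformed. Bmal1 averaged 0.865 TPM in control lungs, 18.4 TPM after LPS alone and 4.86 TPM at the high dose.

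Of 14 markers of airway epithelium 5 fell, 5 when adjusted over the list alone and 8 after scaling, including Scgb3a2 (from 5730 ± 1200 to 1100 ± 654 TPM) and Scgb3a1 (from 2470 ± 696 to 584 ± 298 TPM). The list test pointed down (adjusted p = 5.3e-09, scaled 0.000101, adjusted p = 0.449 with an estimated correlation). Of 11 cardiac muscle markers 3 fell, 0 when adjusted over the list alone and 7 after scaling, and the test pointed down (adjusted p = 6.02e-07, scaled 0.00441, adjusted p = 0.604 with an estimated correlation). Their largest decrease, that of Myl7, was −1.73 and −1.46 without Control replicate 4, where none of the 11 passed. Among 18 monocyte and macrophage markers 14 rose, 15 when adjusted over the list alone and 3 after scaling, for example Cd68 (log2 fold change 2.57). Cell cycle genes rose in 15 of 17 cases, 16 when adjusted over the list alone and 3 after scaling, among them Mcm5, a part of the replicative helicase (log2 fold change 1.93). LPS replicate 3 stood apart in this list with a score of 1.58, against at most 0.336 in the other LPS libraries, and without it the median of the list went from 0.94 to 0.61. The 7 adipose markers tested down with an adjusted p = 0.0248, an adjusted p = 0.514 after scaling and an adjusted p = 0.998 with an estimated correlation, and none of them passed. Their median was 0.06 and their mean −0.02, beside LPS replicate 3 with a score of 2.6 against −0.979 to −0.187 in the other LPS libraries. Without that library the median was −0.43, the mean −0.68 and the adjusted p 0.000134, and 1 member fell. The test no longer passed without Control replicate 4 (adjusted p = 0.0698, median 0.30), LPS replicate 2 (adjusted p = 0.119, median 0.27) or LPS replicate 4 (adjusted p = 0.0827, median 0.31). Across the 32 lists the median, the mean and the direction of the test differed in sign for 12, of which 2 had called tests. The other 10 included the cytokines and chemokines, with a median of 2.80 and a test that pointed down without passing (adjusted p = 0.733). After scaling that test pointed up and passed (adjusted p = 0.00688), and in the TPM as deposited it had an adjusted p = 0.998 with an estimated correlation. Another 7 lists passed only after scaling, all up, which were the interferon-stimulated genes (0.00329), anti-inflammatory feedback genes (0.0117), leukocyte adhesion molecules (0.00119), NRF2 antioxidant genes (0.00218), cell cycle genes (0.0103), neutrophil markers (0.000101) and recruited monocyte and macrophage markers (0.0126). With an estimated correlation, run for the lists on the TPM as deposited only, each of these 7 lists had an adjusted p = 0.998. Of the 6 called lists 3 were shared with the 11 called after scaling. Skeletal muscle transcripts stood apart in LPS replicates 1 and 3, with the muscle actin Acta1 at 1990.25 and 1295.85 TPM, and in AEAA_low replicate 5, with 470.2 TPM.

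Each dose was compared with LPS alone to ask how lungs with prior intake of the extract differed after LPS. No group received the extract without LPS. An effect of the extract on the lung itself therefore cannot be told apart from a changed response to LPS, also for genes counted as moved back. At the low dose, Lama5, a chain of basement membrane laminin, fell from 86.3 ± 12.6 TPM (SD, n = 5) to 36.7 ± 6.08 TPM (SD, n = 5), with a log2 fold change of −1.22 (adjusted p = 0.0065, scaled 0.0088). The transcription factor Klf4 fell from 166 ± 27.4 to 76.7 ± 26.6 TPM (log2 fold change −1.16, adjusted p = 0.013, scaled 0.043). Control lungs held 30.9 TPM of Lama5 and 81.5 TPM of Klf4. The centrosome-associated gene Tacc2 (log2 fold change −1.12) and the peptidase gene Pgpep1 also fell, under both scalings. Among the largest increases were the pseudogenes Pin4-ps, Rps13-ps2, Ubb-ps and Rpl36-ps12, whose reads can come from near-identical parent genes. The low-dose calls followed transcript length. After scaling 180 genes were higher and 2 lower in the shortest of 10 length bins (median 1010 nucleotides), and 0 were higher and 30 lower in the longest. The Spearman rho of the scaled fold change with length was −0.32 across genes, which are not independent replicates. Clec7a, the fungal sensor Dectin-1, rose by 1.66 (adjusted p = 0.025), a call that was lost without LPS replicate 4 (1.63), LPS replicate 5 (1.68) or AEAA_low replicate 3 (1.42).

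In total 1892 genes passed at the low dose, 220 higher and 1672 lower, around a median log2 fold change of −0.20. After scaling 408 passed, 310 higher and 98 lower, and 299 of them were shared with the same sign. Groups did not overlap for 1795 genes (10.1%) in the TPM as deposited, where chance gives 0.794% for a single gene. The median-of-ratios factors did not overlap either (0.9455 to 1.065, against 1.083 to 1.269 with LPS alone), so the chance value does not judge this count. None of the 21 cytokines and chemokines passed, 0 when adjusted over the list alone and 0 after scaling. Their median was 1.40 above that of all genes, and the list test pointed up with an adjusted p = 1.41e-07 (scaled 0.00375) and an adjusted p = 0.702 with an estimated correlation. In all 9 of the 32 lists tested up at the low dose. Interferon-stimulated genes had an adjusted p = 1.41e-07, inflammasome genes 0.000423 and oxidant and nitric oxide enzymes 0.0185. Among cell type markers, alveolar macrophages had an adjusted p = 1.28e-06, recruited monocytes and macrophages 0.000423, T and NK cells 0.000834, erythroid cells 0.00111 and neutrophils 0.0202. With an estimated correlation these adjusted p lay between 0.473 and 0.928. After scaling 7 of the 9 lists passed, and the oxidant enzymes (adjusted p = 0.261) and the neutrophil markers (adjusted p = 0.549) did not. No member of these lists passed, and 1 T and NK cell marker rose after scaling. Without LPS replicate 3, 2 alveolar macrophage markers rose, 3 when adjusted over the list alone, and without LPS replicate 2, 1 T and NK cell marker rose, 1 when adjusted over the list alone. When adjusted over the list alone, 4 erythroid markers rose and 1 monocyte and macrophage marker fell without LPS replicate 4. The oxidant enzymes did not pass without LPS replicate 2 (0.0912), LPS replicate 4 (0.173), AEAA_low replicate 4 (0.0808) or AEAA_low replicate 5 (0.0538). The neutrophil markers did not pass without the same libraries (0.13, 0.315, 0.0808 and 0.0538), nor the erythroid markers without LPS replicate 3 (0.0821) or AEAA_low replicate 2 (0.0552). The low dose included 1 library with near-control Cxcl2 and the LPS group 2, which stood beside these immune lists. Of 15 immediate early genes 2 fell, 2 when adjusted over the list alone and 0 after scaling, with the antiproliferative gene Btg2 going from 158 ± 33.2 to 98.1 ± 8.9 TPM. The count was 1 without LPS replicate 4 or LPS replicate 5 and 4 without AEAA_low replicate 5, and when adjusted over the list alone 5 without LPS replicate 5 and 4 without AEAA_low replicate 5. Of 16 endothelial markers 3 fell, 6 when adjusted over the list alone and 0 after scaling. None fell without LPS replicate 4, LPS replicate 5 or AEAA_low replicate 2, and 1 without AEAA_low replicate 3, where 3 fell when adjusted over the list alone, or AEAA_low replicate 5. In the list of LPS sensing and NF-kB genes 3 of 24 fell, 3 when adjusted over the list alone and 0 after scaling, with Rela, the p65 subunit of NF-kB, going from 118 ± 19.9 to 68.2 ± 6.58 TPM. In that list 1 fell without LPS replicate 3, LPS replicate 4, LPS replicate 5, AEAA_low replicate 2 or AEAA_low replicate 3, and 1 when adjusted over the list alone without LPS replicate 3, LPS replicate 5, AEAA_low replicate 1 or AEAA_low replicate 3. The count of all genes depended on single libraries. It was 1254 without LPS replicate 2, 551 without LPS replicate 4, 608 without LPS replicate 5, 538 without AEAA_low replicate 2, 697 without AEAA_low replicate 3 and 976 without AEAA_low replicate 5.

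At the mid dose no gene passed by limma, with 625 genes at an unadjusted p below 0.05, 541 after scaling and 546 after upper-quartile scaling, under which no gene passed either. The smallest adjusted p was 0.139. By the rule for named genes Cmc2, a mitochondrial assembly gene with 11.6 ± 1.02 TPM (SD, n = 5) against 7.61 ± 0.958 TPM (SD, n = 5) with LPS alone, Rasl11a and Cdc25c had the smallest p, and none of these passed. The median log2 fold change of all genes was −0.04, and groups did not overlap for 46 genes (0.258%), where chance gives 0.794%. The 17 cell cycle genes tested down with a median of −0.41 (adjusted p = 6.84e-06, adjusted p = 0.597 with an estimated correlation). This rested on LPS replicate 3, without which the median was −0.15 and the test did not pass (adjusted p = 0.439). The 12 type I alveolar markers tested up with a median of 0.18 (adjusted p = 0.000404, adjusted p = 0.597 with an estimated correlation), and with 0.04 without LPS replicate 3, where they did not pass (adjusted p = 0.0901). Skeletal muscle markers tested down (adjusted p = 0.000404, adjusted p = 0.597 with an estimated correlation), beside the muscle transcripts of LPS replicates 1 and 3, and did not pass without LPS replicate 1 (adjusted p = 0.114). Cytokines and chemokines tested up with a median of 0.39 (adjusted p = 0.0247, adjusted p = 0.946 with an estimated correlation). They did not pass without LPS replicate 2 (adjusted p = 0.502), LPS replicate 4 (adjusted p = 0.596), AEAA_mid replicate 2 (adjusted p = 0.761), AEAA_mid replicate 3 (adjusted p = 0.388) or AEAA_mid replicate 5 (adjusted p = 0.427), and their median then lay between −0.10 and 0.09. Alveolar macrophage markers (median 0.31, adjusted p = 0.000586), cardiac muscle markers (median 0.81, adjusted p = 0.000404) and erythroid markers (median 0.48, adjusted p = 0.00243) also tested up, and mesothelial markers tested down (median −0.62, adjusted p = 0.00369). All 4 had an adjusted p = 0.597 with an estimated correlation. After scaling 7 of the 8 lists called at the mid dose passed, and the cytokines and chemokines did not (adjusted p = 0.208). The macrophage markers did not pass without LPS replicate 2 (adjusted p = 0.141), the cardiac markers without AEAA_mid replicate 4 (adjusted p = 0.053) and the erythroid markers without LPS replicate 3 (adjusted p = 0.634). The mesothelial list was the 1 of 8 called lists that passed without any single library of both groups. No member of these lists passed, 0 when adjusted over the list alone and 0 after scaling. When adjusted over the list alone, 1 mesothelial marker fell without LPS replicate 5 and 2 without AEAA_mid replicate 4. In the same way 4 skeletal muscle markers fell without LPS replicate 2 or LPS replicate 4 and 5 without LPS replicate 5.

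At the high dose the clock activators fell back toward the control level. Bmal1 fell from 18.4 ± 5.32 TPM (SD, n = 5) with LPS alone to 4.86 ± 2.58 TPM (SD, n = 5), against 0.865 ± 0.163 TPM (SD, n = 4) in control lungs, with a log2 fold change of −1.80 (adjusted p = 0.0014, scaled 0.0079). Npas2 fell from 6.98 ± 1.84 to 1.72 ± 0.635 TPM (log2 fold change −1.55, adjusted p = 0.00094, scaled 0.0019), and Clock by −0.63 (adjusted p = 0.0011). The matrix protein gene Spon2 fell from 30.6 ± 12 to 9.17 ± 3.9 TPM (log2 fold change −1.64, adjusted p = 0.0015). Genes of the small and large ribosomal subunits were among the largest increases, with Rps19 from 641 ± 43.7 to 1080 ± 174 TPM (log2 fold change 0.73, adjusted p = 0.001) and Rpl38 from 1110 ± 150 to 1810 ± 250 TPM (log2 fold change 0.70, adjusted p = 0.00094). Rpl37rt, Rps27rt, Rpl22-ps1 and Rps23-ps1 also rose, and these are retrogenes or pseudogenes whose reads can come from their parent genes.

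In total 4919 genes passed at the high dose, 366 higher and 4553 lower, around a median log2 fold change of −0.27. After scaling 1594 passed, 1011 higher and 583 lower, and 940 of them were shared with the same sign. Groups did not overlap for 1780 genes (9.99%) in the TPM as deposited, where chance gives 0.794% for a single gene. The median-of-ratios factors did not overlap either (0.8868 to 1.072, against 1.083 to 1.269 with LPS alone), so the chance value does not judge this count. Several lists held decreases under both scalings. Of 15 fibroblast and smooth muscle markers 9 fell, 9 when adjusted over the list alone and 3 after scaling, among them the collagen gene Col1a1 (from 103 ± 25.8 to 50.5 ± 2.59 TPM) and the growth factor receptor Pdgfrb (from 53 ± 8.68 to 27.5 ± 5.94 TPM). The list test pointed down (adjusted p = 0.0472, scaled 0.00844, adjusted p = 0.94 with an estimated correlation), and did not pass without LPS replicate 1 (adjusted p = 0.118), AEAA_high replicate 2 (adjusted p = 0.126) or AEAA_high replicate 3 (adjusted p = 0.0801). Of 16 endothelial markers 7 fell, 9 when adjusted over the list alone and 2 after scaling, and Cdh5 went from 353 ± 75.6 to 191 ± 38.2 TPM. The count of 7 was 4 without LPS replicate 4 or AEAA_high replicate 3. Among 15 immediate early genes 6 fell, 7 when adjusted over the list alone and 2 after scaling. The transcription factor Fos went from 83.5 ± 42.6 to 22.6 ± 7.42 TPM (log2 fold change −1.71, adjusted p = 0.0042). The phosphatase Dusp1, a brake on MAP kinases, fell by −1.19 (adjusted p = 0.0011), and Sod3, the extracellular superoxide dismutase, by −0.79 (adjusted p = 0.0019), both also after scaling. Of the 20 genes of the NRF2 antioxidant response, which include Sod3, 1 rose and 1 fell, 0 and 1 when adjusted over the list alone, and 2 and 1 after scaling. None of them rose without LPS replicate 3 or AEAA_high replicate 4, and 2 fell without LPS replicate 1 or AEAA_high replicate 2 and 3 without AEAA_high replicate 1. When adjusted over the list alone, 1 rose without LPS replicate 1, LPS replicate 5, AEAA_high replicate 2 or AEAA_high replicate 3, and 2 fell without LPS replicate 1 and 3 without AEAA_high replicate 1. In the type II alveolar list 4 of 14 fell, 5 when adjusted over the list alone and 2 after scaling, with the surfactant lipid transporter Abca3 from 123 ± 16 to 66.6 ± 23.1 TPM, and 7 fell without AEAA_high replicate 1.

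None of the 21 cytokines and chemokines passed at the high dose, 0 when adjusted over the list alone and 0 after scaling, and none of the 20 neutrophil markers did, with 1 that fell without LPS replicate 1 or AEAA_high replicate 1. Il1b had an adjusted p = 0.96 and S100a9 an adjusted p = 1. The cytokine list tested up (adjusted p = 0.00153, scaled 0.503, adjusted p = 0.94 with an estimated correlation), with a median 0.63 above that of all genes, beside 2 libraries with near-control Cxcl2 in each group. The neutrophil list also tested up (adjusted p = 0.0333, scaled 0.723, adjusted p = 0.94 with an estimated correlation), with a median of 0.02 and a mean of −0.02. It did not pass without LPS replicate 2 (adjusted p = 0.0649), LPS replicate 4 (adjusted p = 0.172), AEAA_high replicate 2 (adjusted p = 0.198), AEAA_high replicate 3 (adjusted p = 0.158) or AEAA_high replicate 5 (adjusted p = 0.0577), where the median was negative. Of 17 cell cycle genes 6 fell, 15 when adjusted over the list alone and 0 after scaling. Without LPS replicate 3, which stood apart in this list, 1 fell, 0 when adjusted over the list alone, and the median went from −0.64 to −0.37. The count was also 1 without AEAA_high replicate 4 and 2 without AEAA_high replicate 3, and it was 12 without LPS replicate 1 and 11 without LPS replicate 5. When adjusted over the list alone it was 0 without AEAA_high replicate 1 or AEAA_high replicate 4 and 5 without LPS replicate 4. Of 14 airway markers Scgb3a1, the secretoglobin of the upper airways, rose from 584 ± 298 to 1650 ± 820 TPM (log2 fold change 1.52, adjusted p = 0.015), 1 when adjusted over the list alone and 1 after scaling. Adjusted over the list alone it did not pass without LPS replicate 2, LPS replicate 3, LPS replicate 4, AEAA_high replicate 3 or AEAA_high replicate 4. Without AEAA_high replicate 1, 2 airway markers fell, 2 when adjusted over the list alone. With sample quality weights Scgb3a1 had a log2 fold change of 1.02 and did not pass. That list tested up (adjusted p = 0.0472, scaled 0.503, adjusted p = 0.94 with an estimated correlation) although its median was −0.11. It did not pass without LPS replicate 2 (adjusted p = 0.0558), LPS replicate 3 (adjusted p = 0.0618), LPS replicate 4 (adjusted p = 0.0533), AEAA_high replicate 1 (adjusted p = 0.281) or AEAA_high replicate 4 (adjusted p = 0.31). Cardiac muscle markers tested up without a member that passed (adjusted p = 0.0361, scaled 0.503, adjusted p = 0.94 with an estimated correlation), and not without LPS replicate 2 (adjusted p = 0.0649), AEAA_high replicate 1 (adjusted p = 0.0897) or AEAA_high replicate 4 (adjusted p = 0.415). Of the 5 lists called at the high dose only the fibroblast and smooth muscle markers also passed after scaling. The cell cycle (adjusted p = 0.00987), immediate early (adjusted p = 0.0498) and endothelial lists (adjusted p = 0.0439) passed only after scaling, all down. With an estimated correlation, run for the lists on the TPM as deposited only, each of them had an adjusted p = 0.94. Across the 32 lists the median, the mean and the test differed in sign for 18. The scaled fold changes declined with transcript length, with a Spearman rho of −0.40 across genes, which are not independent replicates. In the shortest of 10 length bins 420 genes were higher and 2 lower, and in the longest 7 were higher and 170 lower.

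**Figure D3:**
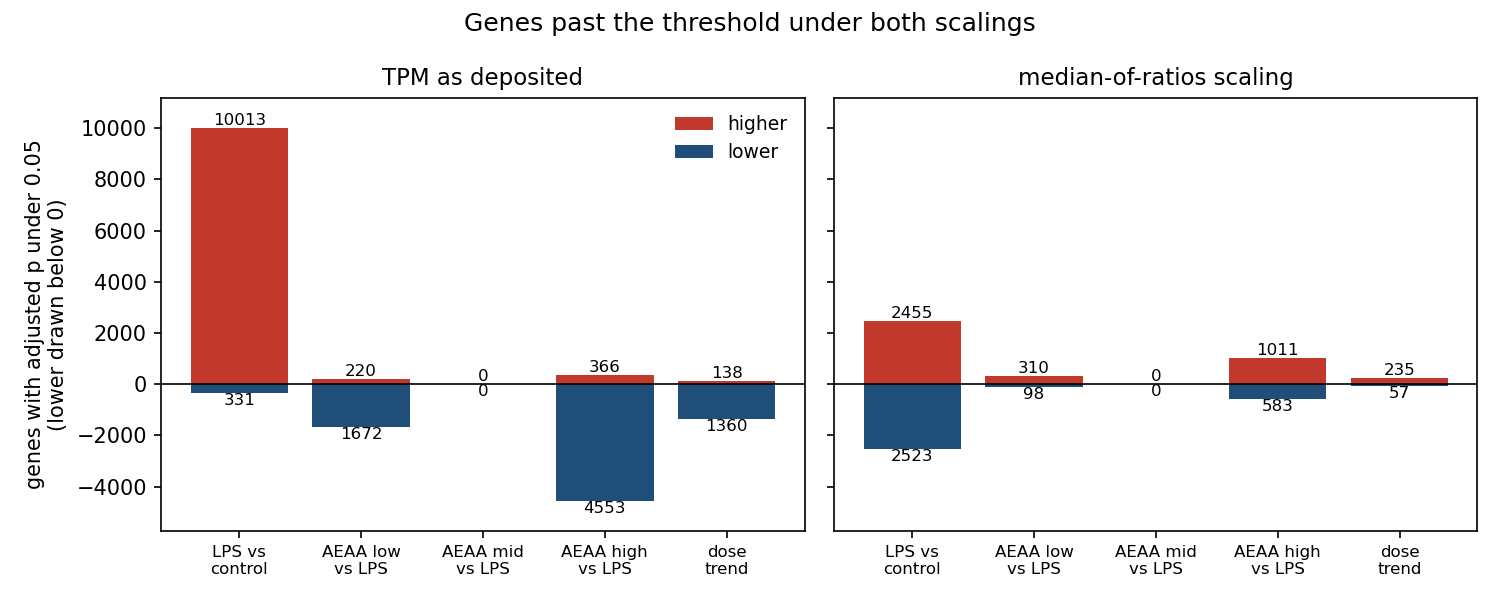
Genes past an adjusted p of 0.05 in each comparison, higher drawn above 0 and lower below it, for the TPM as deposited and after median-of-ratios scaling. For the high dose 366 genes were higher and 4553 lower in the deposited TPM, and 1011 higher and 583 lower after scaling.

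**Figure D4:**
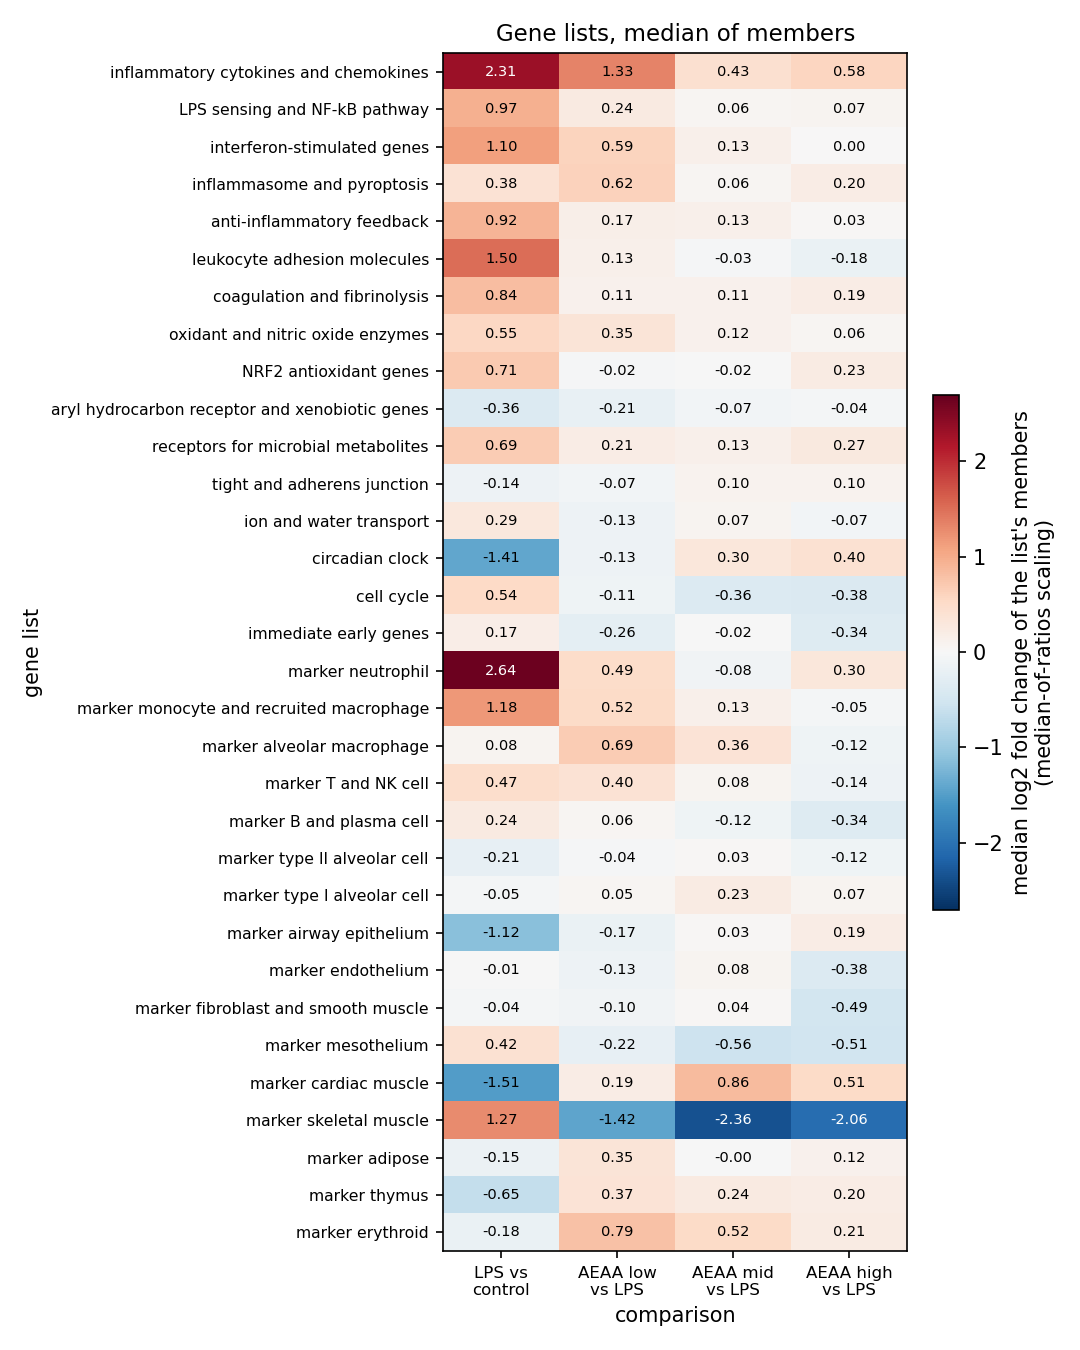
Median log2 fold change of the members of each of the 32 gene lists after median-of-ratios scaling, by comparison. The neutrophil markers had a median of 2.64 for LPS against control and 0.30 for the high dose against LPS.

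**Figure D5:**
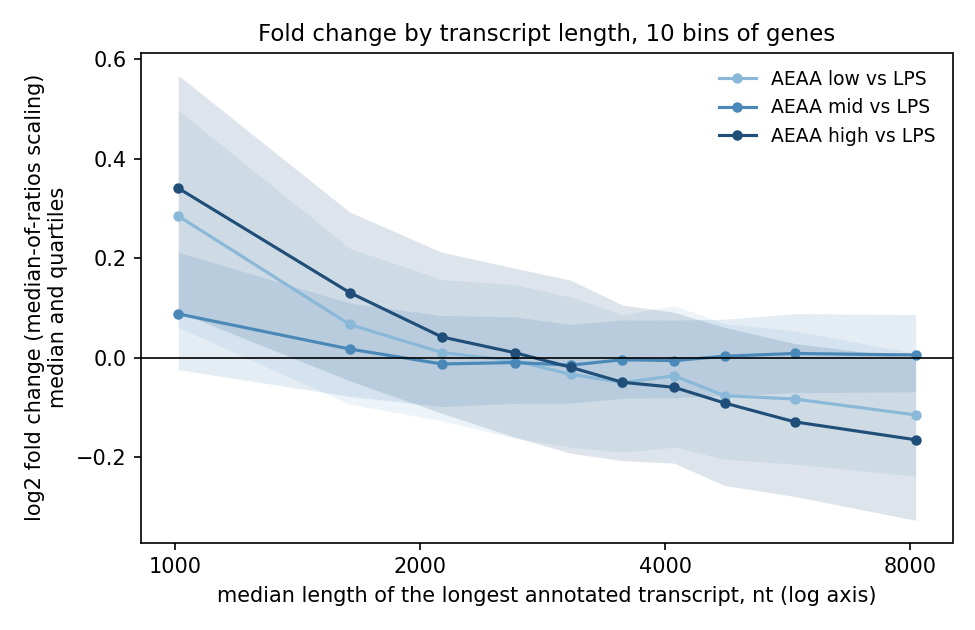
Scaled log2 fold change by length of the longest transcript, on a log axis in nucleotides, with the median and quartiles of 10 bins of genes per dose. The Spearman rho with length across genes was −0.32 at the low dose, −0.07 at the mid dose and −0.40 at the high dose.

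The doses were also compared with each other. For the linear trend over the 4 challenged groups 1498 genes passed, 138 higher and 1360 lower, and after scaling 292 passed, 235 higher and 57 lower. Npas2 had the smallest p, with a slope of −0.51 per dose step (adjusted p = 0.0042, scaled 0.0098), and averaged 6.98 TPM with LPS alone, 5.05 TPM at the low dose, 3.23 TPM at the mid dose and 1.72 TPM at the high dose. Next came the guanine nucleotide exchange factor Vav2, the TGF-beta mediator Smad3, the actin-associated gene Afap1l2 and the complement component C7. All had a negative slope and passed after scaling. A linear trend can pass where the high dose alone differs, so it does not show a change at each step. Against LPS alone 1892, 0 and 4919 genes passed at the low, mid and high dose. The medians of all genes were −0.20, −0.04 and −0.27, so the mid dose broke the order. Any dose differed from LPS alone for 3961 genes, with C7 and the matrix protein gene Svep1 among the 5 smallest p, and for 1283 after scaling. The high dose differed from the low dose for 1 gene, with 1539 genes at an unadjusted p below 0.05 and 5 passing after scaling. That gene, Lipa, the lysosomal acid lipase, was named after its values were seen and averaged 46.6 ± 2.95 TPM (SD, n = 5) at the low dose and 26.4 ± 4.82 TPM (SD, n = 5) at the high dose (log2 fold change −0.82, adjusted p = 0.028). It did not pass without AEAA_low replicate 1 (adjusted p = 0.091), AEAA_low replicate 4 (adjusted p = 0.054), AEAA_low replicate 5 (adjusted p = 0.10), AEAA_high replicate 3 (adjusted p = 0.053) or AEAA_high replicate 4 (adjusted p = 0.053). Nor did Lipa pass with the replicate number as a block (adjusted p = 0.085), in a fit to the compared groups alone (adjusted p = 0.24), without a filter (adjusted p = 0.068) or with a pseudocount of 0.1 without a filter (adjusted p = 0.08). The 5 genes after scaling were Lipa, Wee1, Shisa3, Rpl13a and H2-Q2, also named after their values were seen, and with sample quality weights 823 genes passed. More genes passed at one dose than at another, and how far the responses to both doses differed depended on these settings. The trend count rested on single libraries, with 387 without LPS replicate 3, 145 without LPS replicate 4, 173 without LPS replicate 5, 976 without AEAA_mid replicate 1, 888 without AEAA_mid replicate 2, 3833 without AEAA_high replicate 1, 633 without AEAA_high replicate 2, 321 without AEAA_high replicate 3, 121 without AEAA_high replicate 4 and 107 without AEAA_high replicate 5.

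The last question was which LPS-changed genes each dose moved back toward control. At the low dose 1679 genes moved back and 15 moved further, at the mid dose none moved in either direction, and at the high dose 4225 moved back and 40 moved further. By the rule, the genes with the largest LPS change among them were Mrip-ps, Pin4-ps, the lipase gene Lipe, Phospho1 and Derl3 at the low dose. At the high dose they were Bmal1, Ppp1ccb, Spon2, Commd1b and the lubricin gene Prg4. Of these, 1622 at the low dose and 4146 at the high dose rose and then fell, where lists drawn independently would share 939 and 2558. The other 57 and 79 fell and then rose, where independent lists give 4.09 and 6.80. After scaling 327 and 1010 genes moved back, with 61 and 361 that rose and then fell where independent lists give 13.5 and 80.3, and 266 and 649 that fell and then rose where they give 43.9 and 143. Simulated dose groups without any effect gave a median of 0 moved-back genes, with at most 716 in the TPM as deposited and at most 174 after scaling. The simulated groups held no shift of whole libraries and none along transcript length, while the low-dose and high-dose libraries showed both against LPS alone. The simulations therefore do not tell genes moved back by the extract from genes moved by such shifts. With the LPS libraries split between both comparisons the median count was 52.5 at the low dose and 2100 at the high dose, and after scaling 2.5 and 318. The covariance of both fold changes across genes was −0.0527 at the low dose, −0.0428 at the mid dose and −0.11 at the high dose. Simulated groups averaged −0.0559, in a range of −0.282 to 0.104 that holds the observed value of every dose. The split libraries averaged −0.00454, 0.00539 and −0.0622, in ranges of −0.0924 to 0.153, −0.0743 to 0.146 and −0.14 to 0.0861. The covariance therefore does not separate any dose from a group without effect. The count at the low dose was 475 without LPS replicate 4, 514 without LPS replicate 5, 442 without AEAA_low replicate 2, 617 without AEAA_low replicate 3 and 869 without AEAA_low replicate 5.

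The list scores of single libraries differed between LPS and control for 23 of 32 lists by the exact permutation test, in which 0.00794 is the smallest p that 126 assignments allow, and for none of them after scaling. Between a dose and LPS alone no list score passed, in a test where at least 6 of the 32 lists must reach the smallest p for any to pass. The score of ion and water transport genes at the low dose and that of immediate early genes at the high dose were at that smallest p, with an adjusted p = 0.254 and an adjusted p = 0.212 by exact permutation. Of 225 calls on named genes 77 were lost without some library and 125 after scaling, and none changed sign.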

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

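The tests of near-control inflammatory transcripts given here were chosen after the result was seen, and the counts of other splits of the samples were planned. In 175 groups of libraries over 35 quantities, 10 held a library far from the others of its group, and chance gives about 1 in 20 groups.

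AEAA_low replicate 1 stood far below the other low-dose libraries in the scores of 4 immune lists. Its score was −1.87 for cytokines and chemokines, where the others lay between 1.69 and 2.37, and −0.558 for LPS sensing and NF-kB genes, where they lay between 0.416 and 0.76. It was −0.954 for anti-inflammatory feedback genes (others 0.547 to 1.08) and −0.704 for neutrophil markers (others 0.806 to 1.14).

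This library is 1 of the 7 challenged libraries with Cxcl2 between 0.09 and 1.37 TPM. A swap with a control library would need a control library with high Cxcl2, and 0 were found. A control mouse under a challenged label would show the control level of Slc7a11, Gsta13 and Bmal1, and 0 of the 7 libraries had any of these within the control range. These genes were chosen after the result was seen and separate every LPS library from control. For LPS replicates 2 and 4 the count was therefore fixed in advance. For the libraries with extract it argues against a mouse kept and collected with the controls. It cannot exclude a mouse without LPS that was otherwise handled with the challenged mice. What stays open is that LPS may not have reached these lungs in full: 0 of the 7 had Cxcl2, Tnf, Saa3, Lcn2 and Csf3 all above the control range, with 6, 5, 2, 7 and 1 of them above it gene by gene. Lcn2 in all 7 lay between 217.25 and 310.32 TPM, above the 95.5 to 140.47 TPM of control libraries, and nothing in the labels records delivery, so a small delivered dose and a weak response of the mouse cannot be told apart. The extract as a biological cause was not tested, since LPS replicates 2 and 4, which had none, are among the 7.

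The other libraries that stood apart are given as values. Control replicate 2 had a cytokine and chemokine score of −2.39, against −2.62 to −2.59 in the other control libraries. Control replicate 1 had a circadian clock score of −0.0659, against 0.263 to 0.277. LPS replicate 3 had a cell cycle score of 1.58, against −1.23e-05 to 0.336, and an adipose score of 2.6, against −0.979 to −0.187. The same library held 1.59% of its TPM in immunoglobulin transcripts, against 0.153% to 0.366%. AEAA_low replicate 5 had a skeletal muscle score of 4.66, against −1.13 to −0.624. In the direct test of the high against the low dose Lipa passed, with a log2 fold change of −0.815 (limma adjusted p = 0.028). It did not pass with the replicate number as a block, in a fit to the compared groups alone, without a filter, with a pseudocount of 0.1 without a filter, after scaling without the libraries with muscle transcripts, or without AEAA_low replicate 1, 4 or 5 or AEAA_high replicate 3 or 4. Its log2 fold change without 1 library lay between −0.875 and −0.694. Of 100 splits 8, the real one included, gave at least 1 gene in this comparison, whichever gene it was, so chance is not excluded.

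Other splits of the samples tested whether chance can give such counts. For LPS against control 1 of 100 splits, the real one, gave as many genes as the 10344 found, with at most 8945 in the others. For the low dose the count of 1892 was reached by 1 of 100 splits (highest other 6), for any dose 3961 by 1 (highest other 3666), and for the trend 1498 by 1 (highest other 738). The high dose count of 4919 was reached by 3 of 100 splits, with 5620 in the largest. For these 5 counts in the TPM as deposited, fewer than 0.05 of the splits gave as many genes, without correction over the counts tested. For the high dose this did not hold after scaling. Chance is not excluded for the high against the low dose. There 8 of 100 splits, the real one included, gave at least the 1 gene found, and 1 of them gave 1683. The moved-back count at the low dose was 1679, reached by 1 of 100 splits (highest other 5), and at the high dose 4225, reached by 1 (highest other 4012). At the mid dose the counts of genes and of moved-back genes were 0, which each of the 100 splits reaches whatever it gives, so the splits say nothing about chance there. The largest counts in these splits were 29 and 3.

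After scaling, 1 of 100 splits reached the 4978 genes of LPS against control (highest other 4922), and 1 of 100 reached the 408 of the low dose (highest other 2). For the high dose 5 of 100 splits reached the 1594 genes, so chance is not excluded there. The largest of these splits gave 4758 genes, several times the real count, which points to a structure of the samples that the groups do not follow. The first principal component, the axis of largest variance (37.8%), put the 7 challenged libraries with low Cxcl2 at −52.93 to −9.09. The other challenged libraries lay at 18.13 to 50.76. Whether this division gave the large count was not tested.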

How the results depend on the processing

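The alternatives without the libraries that hold muscle transcripts, without Scgb1a1, and with both median-of-ratios scaling and those libraries left out were chosen after the result was seen. All values are from limma unless stated. A count-based DESeq2 fit was planned and not run, since the table used here holds TPM, and the planned voom weights were replaced by sample quality weights. The unknown depth limits every value at low TPM.

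The direction of the split of calls depended on scaling. Without Scgb1a1 it was largely that of the TPM as deposited, with 5523 higher and 1027 lower for LPS against control, 262 and 1522 at the low dose and 418 and 4158 at the high dose. With a filter on mean TPM every count of genes stayed within 1.5 times its main value. Of 225 calls on genes named by the rule, 100 were kept after median-of-ratios scaling and 125 lost, 101 kept and 124 lost after upper-quartile scaling, and 155 kept and 70 lost without a filter. With a pseudocount of 0.1 without a filter 50 were lost, in a fit to the compared groups alone 38, with sample quality weights 9 and with the replicate number as a block 5, and none reversed.

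Counts are given in the order LPS against control, low dose, mid dose, high dose, any dose, trend, high against low dose, and genes moved back at the low, mid and high dose, and only those that moved by over 1.5 times are listed. Median-of-ratios scaling gave 4978 for LPS against control, 408 low, 1594 high, 1283 any dose, 292 trend, 5 high against low, and 327 and 1010 moved back at the low and high dose. Upper-quartile scaling gave 5027, 482, 1609, 1345, 306 and 4, and 385 and 1069 moved back. An absolute log2 fold change of 1 or more left 3118 for LPS against control, 53 low, 187 high, 2 trend, 0 high against low, and 32 and 113 moved back, as fewer genes can pass. Without a filter the low dose had 347, the high dose 3247, any dose 2413, the trend 95, high against low 0, and 285 moved back at the low dose. A pseudocount of 0.1 without a filter gave 396 low, 1 mid, 2568 any dose, 138 trend, 0 high against low, and 323 and 1 moved back at the low and mid dose. Sample quality weights gave 3443 low, 1 mid, 6926 any dose, 4993 trend, 823 high against low, and 2940 and 1 moved back at the low and mid dose. A fit to the compared groups alone gave 1 mid, 1961 high, 938 trend, 0 high against low, and 1850 moved back at the high dose. The replicate number as a block gave 973 for the trend and 0 for high against low, and it pairs no mice: of 46 pairs of libraries with the same number 20 correlated above 0.1, from −0.45 to 0.64. Without the libraries with muscle transcripts there were 6 genes at the mid dose, 2 high against low, and 6 moved back at the mid dose. Without Scgb1a1 there were 6550 for LPS against control and 9 high against low. With scaling and those libraries left out there were 2727, 170, 4, 967, 786, 211 and 3, and 157, 3 and 582 moved back. The cause of these shifts was not tested, except that Scgb1a1 alone accounts for part of that in LPS against control, where the median of all genes went from 0.55 to 0.22 without it.

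Of 128 list tests 28 passed, 29 after scaling and 0 with an estimated correlation. Both scalings shared 18 calls, 10 were lost and 11 gained after scaling. For LPS against control 3 were lost and 8 gained, at the low dose 2 and 0, at the mid dose 1 and 0, and at the high dose 4 and 3. Without some library of the groups compared, 2 of 6 calls were lost for LPS against control, 3 of 9 at the low dose, 7 of 8 at the mid dose and 4 of 5 at the high dose. The list scores passed in 23 cases by exact permutation and in 0 after scaling.

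Leaving out each library in turn gave 9127 to 10264 genes for LPS against control, 3295 to 6358 at the high dose, 2840 to 5246 for any dose, 2998 to 4821 moved back at the high dose, and 21 to 38 list tests. The low dose ranged from 538 to 2417, with 1254 without LPS replicate 2, 551 without LPS replicate 4, 608 without LPS replicate 5, and 538, 697 and 976 without AEAA_low replicates 2, 3 and 5. The mid dose ranged from 0 to 2, with 1 without LPS replicate 1 or AEAA_mid replicate 5 and 2 without LPS replicate 4, and its moved-back genes had the same range and values. The trend ranged from 107 to 3833, with 387, 145 and 173 without LPS replicates 3, 4 and 5, 976 and 888 without AEAA_mid replicates 1 and 2, and 3833, 633, 321, 121 and 107 without AEAA_high replicates 1, 2, 3, 4 and 5. High against low ranged from 0 to 5, with 0 without AEAA_low replicates 1 or 5 or AEAA_high replicates 3 or 4, 2 without AEAA_low replicates 2 or 3 or AEAA_high replicate 5, and 5 without AEAA_high replicate 1. Moved-back genes at the low dose ranged from 442 to 2163, with 475 and 514 without LPS replicates 4 and 5 and 442, 617 and 869 without AEAA_low replicates 2, 3 and 5. The list scores ranged from 12 to 24, with 12 without Control replicate 1, 13 without Control replicates 3 or 4 and 24 without Control replicate 2. Without a control library 56 assignments allow 0.0179 as the smallest p, which at least 12 lists must reach for any to pass, and without an LPS library 70 allow 0.0286, which 19 must reach. Part of this range is therefore set by the design, and it does not measure dependence on single libraries.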

Other observations

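The tests of the clock genes were chosen after the result was seen, and those of the ribosomal protein genes were fixed before their values were computed.

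Pathway sets of the deposited annotation pointed to genes of translation and respiration. At the high dose 102 of 129 ribosome genes rose and 0 fell after scaling, with a median of 0.59, and 68 rose and 4 fell in the TPM as deposited, with a median of 0.28. Of 125 oxidative phosphorylation genes, which build the respiratory chain, 69 rose and 1 fell after scaling (camera adjusted p = 1.6e-26, adjusted p = 0.24 with an estimated correlation). At the low dose 57 of 129 ribosome genes and 37 of 125 oxidative phosphorylation genes rose after scaling, with an adjusted p = 0.43 with an estimated correlation for both. For LPS against control 2 ribosome genes rose and 70 fell after scaling, and the direction flipped in the TPM as deposited, where 61 rose and 8 fell. The Notch pathway pointed down at the high dose with 9 of 59 genes that fell and 1 that rose after scaling (adjusted p = 5.5e-05, adjusted p = 0.24 with an estimated correlation). For LPS against control 119 of 307 pathways tested higher after scaling and 19 lower, with the Toll-like receptor and NF-kappa B pathways among those higher. After scaling 26 tested higher and 56 lower at the high dose, 30 and 32 at the low dose, and 5 and 4 at the mid dose. In none of the comparisons did a pathway pass with an estimated correlation.

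The higher ribosomal protein genes at the high dose may reflect a bias by transcript length between libraries rather than the extract. These genes have a median length of 1151 nucleotides, and 248 other genes matched on length and abundance had a median scaled log2 fold change of 0.29, which is 0.489 of that of the ribosomal protein genes. The value lies just below the 0.5 set beforehand for a length bias, and above the bound set for its absence. At the low dose the matched genes had a median of 0.22 against 0.45 for the ribosomal protein genes, and at the mid dose 0.08 against 0.12. Length and function overlap in these genes, so both cannot be told apart. The libraries with muscle transcripts are argued against as the source, since the median without them was 1.15 times that with all libraries. An effect of the dose itself stays open and untested.

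The clock genes differed between control and challenged lungs, and 3 explanations were weighed. An inflammatory response of the same lung cannot be told apart for Bmal1 and Npas2. Of the 7 challenged libraries with low Cxcl2, 0 had either gene within the control range, but all 7 had Lcn2 above it, so these lungs had responded in part. Bmal1 was 4.31 and 8.14 TPM in the mid-dose libraries with low Cxcl2, against 10.74 to 13.68 TPM in the others, and 2.46 and 2.03 TPM at the high dose, against 5.27 to 8 TPM. With LPS alone it was 10.21 and 22.73 TPM in those with low Cxcl2, against 16.81 to 23.32 TPM, and at the low dose 13.62 TPM in the 1 with low Cxcl2, against 5.66 to 14.77 TPM. For the 9 genes of the evening arm an inflammatory response cannot be told apart either. Of those 7 libraries, AEAA_high replicates 1 and 4 had 7 and 5 of these genes within the control range. LPS replicates 2 and 4 had 1 and 0, AEAA_low replicate 1 had 1, and AEAA_mid replicates 1 and 4 had 2 each. The libraries with most of these genes at the control level were thus both from the high dose. A difference in the time of day at collection could give such a pattern and cannot be told apart from the challenge. In all, 14 of 14 clock genes had a scaled fold change of the sign that their morning or evening arm would give, 13 of them past the threshold and Cry1 not (0.11, adjusted p = 0.78). These genes and their arms were chosen from the 17 measured clock genes after the result was seen, so the agreement decides nothing. Of the 3 in neither arm Cry2 fell (−0.70, adjusted p = 0.02), and Per1 (−0.69, adjusted p = 0.23) and Bhlhe40 (0.08, adjusted p = 0.88) did not pass. The labels give no time of collection, so it is confounded with the challenge. At the high dose 3 of the 14 genes passed after scaling, Bmal1, Npas2 and Clock, each against the direction of the LPS change in a comparison that shares the LPS libraries. An effect of LPS or of the extract on the clock stays open and untested.

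The labels give male sex for all mice. The X inactivation transcript Xist lay between 25.82 and 95.49 TPM in all 24 libraries, and the Y-linked Ddx3y reached at most 0.02 TPM, Eif2s3y 0 TPM, Uty at most 0.03 TPM and Kdm5d at most 0.15 TPM. These values argue against the male label and are those of female lungs, in every library.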
